A study of Mus musculus with 2 samples.

How the data were processed

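Adrenal gland RNA of female B6CASTF1/J mice at postnatal day 4 was profiled by long-read RNA sequencing in 2 biological replicates, from 1 µg of total RNA each, per the labels. ERCC spike-in RNAs (Ambion mix 1) and Lexogen spike-ins were added, per the labels. The tables list ERCC spike-ins, and Lexogen spike-ins were not analysed here. For each library the deposited transcript table gives counts, whole reads per transcript model with no normalization and no model below 1 read, as the values show. The deposited tables also give the length and the number of exons of each model, and the deposited annotations give genes, transcripts and exons in mm10. Alignments were made to mm10 and transcripts were compared with GENCODE M21, per the deposited descriptions of the files. Models outside GENCODE were built by TALON, per the source field of the deposited annotations, separately for each library, since their identifiers carry the library's name. The aligner, the sequencing platform and tool versions are not given in the sources used here. No filter on models with few reads is recorded, and 62.7% of the models in replicate 1 and 62.4% of those in replicate 2 had 1 read.

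The counts of all models of a named gene were summed per library. Spike-ins took 1.98% of reads in replicate 1 and 1.71% in replicate 2, and unnamed antisense and intergenic loci 6.68% and 4.85%, and both were left out of the gene totals of 1114771 and 1039687 reads. CPM values were computed from those totals. In the settings with Known transcripts alone, or with Known, NIC and NNC transcripts, levels and ratios were scaled to the reads of those classes on named genes. Coordinates and types of annotated genes come from GENCODE M21 on mm10, and those of unannotated models from the deposited annotations.

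The tests, gene lists, minimum counts, thresholds, the rule for naming genes and most alternatives were fixed before the data were examined. The named genes were the 20 with the highest mean CPM, up to 4 per list by mean CPM, up to 10 per direction with the largest log2 ratio among those past 0.05 and at least 2-fold, panel genes with a dominant isoform share of at most 90% and at least 20 Known reads in each library (up to 15 by Known reads), up to 5 genes with the largest difference in isoform share past the threshold, and the 10 NIC or NNC chains with the most summed reads in both libraries. Other genes in the text were chosen after their values were seen, and some genes that the rule names are not reported here. The lists covered steroidogenesis, cholesterol supply, cortical zones, capsule and stroma, chromaffin cells, neurons, Schwann lineage, endothelium, macrophages, red cells, cell cycle, immediate early genes, imprinted genes, mitochondrial genes, ribosomal proteins, sex-linked genes, an isoform panel, and kidney, adipose tissue, liver, muscle and pancreas.

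Genes with at least 20 summed reads were compared between the libraries by an exact two-sided binomial test against the library totals, with Benjamini-Hochberg adjustment. Log2 ratios have 0.5 count added to each library, and their SE covers counting error. A gene with 0 reads in a library is given a bound against 3 counts in that library, and ratios on 1 to 3 reads carry exact 95% counting intervals. Short and long spike-ins were compared by an exact permutation test, and transcript classes and isoform usage by Fisher's exact test with Benjamini-Hochberg adjustment. A list median was placed among 10000 random lists of equal size matched on mean expression. The biological coefficient of variation is the square root of the common dispersion of edgeR 4.0.16 with TMM scaling in R 4.3.3, and DESeq2 1.42.0 supplied alternative size factors. Shares of reads carry Wilson 95% intervals. Isoform shares use Known reads. Intron chains were matched by coordinates and strand, and NIC and NNC chains of equal reads were compared by Fisher's exact test without adjustment, which was chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

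The procedures were tested on simulated data. For the comparison of genes between the libraries, with 10438 genes tested, 65 of 100 genes changed 2-fold and 100 of 100 changed 4-fold were recovered with 7 false calls. For isoform usage, with 3648 genes, 144 of 200 genes with a shift of 30 percentage points were recovered with 6 false calls. Both of these simulations held counting error alone, so their false calls do not cover the further spread between the real libraries. A simulated biological coefficient of variation of 0.2 was estimated as 0.204 over 10110 genes and of 0.4 as 0.392 over 9948 genes. Alternatives covered scaling, transcript classes, minimum counts, thresholds, depth, mitochondrial genes, splice site tolerance and leaving out each replicate. Alternatives chosen after seeing the data were removing the trend with transcript length and leaving out the listed genes of other tissues.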

Results

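Long-read RNA sequencing was done on the adrenal gland of female mice at postnatal day 4. The mice were B6CASTF1/J, the first generation of a cross between the B6 and Cast strains. The adrenal gland has a steroid-making cortex around a medulla of catecholamine-making chromaffin cells. All samples formed 1 group with 2 biological replicates, so no comparison between conditions exists, and each comparison below describes the tissue or sets the 2 libraries against each other. The sample labels named different animals for the 2 replicates in one field and the same animal number in another, so whether the spread between them is that of separate animals could not be settled, and it may be technical. The table of replicate 1 held 1220468 reads, of which 1114771 fell on named genes, and that of replicate 2 held 1112762 reads, of which 1039687 fell on named genes. Levels are given in CPM, reads scaled to the library's total on named genes, and 1 read was worth 0.897 CPM in replicate 1 and 0.962 CPM in replicate 2. A level given for some transcript classes alone is scaled to the reads of those classes. It is therefore not on the scale of the other levels and is not a part of them. The mean length of the transcript models, weighted by reads, was 2236 bases in replicate 1 and 2321 bases in replicate 2. Transcripts were also counted by the class given in the deposited tables, where Known stands for a match to every annotated splice junction, NIC for new combinations of annotated splice sites and NNC for the use of an unannotated site, although some NIC chains held a site outside their gene's annotation. Wilson intervals and limits for genes without reads cover counting error only.

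Genes of steroid synthesis led the tissue's transcripts. Cyp21a1, the 21-hydroxylase, stood at 8242 CPM ± 383 (SD, n = 2), and Cyp11a1, the cholesterol side-chain cleavage enzyme that opens the pathway, at 8042 ± 679 CPM (SD, n = 2). Hsd3b1, a 3-beta-hydroxysteroid dehydrogenase, reached 4462 ± 255 CPM and Cyp11b1, which makes corticosterone, 4373 ± 199 CPM. With Known transcripts alone, and scaled to Known reads, Hsd3b1 stood at 21.9 CPM, most of its reads being of other classes. Together the 21 steroidogenesis genes took 3.23% of the reads on named genes in replicate 1 (Wilson 95% interval 3.20 to 3.26) and 3.11% in replicate 2 (3.07 to 3.14), and 19 of them had at least 10 reads in both libraries. In GENCODE M21 on mm10, Cyp21a1 (ENSMUSG00000024365.9) lies on chromosome 17 from 34801348 to 34804561, and Cyp11a1 (ENSMUSG00000032323.13) on chromosome 9 from 58006411 to 58027023. Cyp11b1 and Cyp11b2, and likewise Hsd3b1 and Hsd3b6, are close paralogs, and the division of reads between them is uncertain.

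The markers of the cortical zones differed widely in level. Kcnk3, a potassium channel of the zona glomerulosa list, stood at 1579 ± 184 CPM (SD, n = 2), and Cyp11b2, the aldosterone synthase of the outer cortex, at 530 ± 81.5 CPM, 2 others of that list being Wnt4 at 363 ± 73.7 CPM and Dab2 at 127 ± 50.2 CPM, or 72.4 CPM with Known transcripts alone. Of the 14 zona glomerulosa genes 10 had at least 10 reads in both libraries. In the list of the zona fasciculata and the X zone, where 6 of 10 genes did, Cyp11b1 was followed by the transporter Abcb1b at 478 ± 98.5 CPM, Akr1c18 at 221 ± 60.7 CPM and Akr1b7 at 206 ± 24.0 CPM. The cholesterol supply list held 0.359% ± 0.00210 of the reads (SD, n = 2), with 25 of 29 genes at 10 reads or more in both libraries. Its leading members were Apoe at 1589 ± 71.1 CPM, the cholesterol synthesis enzyme Hmgcs1 at 481 ± 40.1 CPM, Npc2 at 178 ± 9.43 CPM and Soat1, which esterifies cholesterol, at 178 ± 3.71 CPM.

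Genes of the medulla also stood at high levels. The granule proteins Chga and Chgb stood at 5569 ± 1367 and 4958 ± 1762 CPM (SD, n = 2), Th, the rate-limiting enzyme of catecholamine synthesis, at 1931 ± 326 CPM and Scg2 at 1145 ± 106 CPM. The 30 chromaffin genes took 1.41% of reads in replicate 1 (1.39 to 1.43) and 1.93% in replicate 2 (1.90 to 1.96), and 27 had at least 10 reads in both libraries. Pnmt, which turns noradrenaline into adrenaline, stood at 562 ± 29.0 CPM. The neuron and sympathoblast list was far lower at 0.0786% ± 0.00354 of reads, with 11 of 15 genes detected in both libraries and Tubb3 at 179 ± 3.67, Prph at 122 ± 0.743, Nefl at 97.9 ± 18.8 and Nefm at 87.4 ± 13.4 CPM. Among 11 Schwann lineage genes 6 were detected in both, among them the myelin gene Mbp at 34.2 ± 7.51 CPM and Gfra3 at 15.6 ± 7.11 CPM.

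The lists of stroma, vessels and blood took smaller shares of the reads. Such shares depend on the genes listed and do not measure the make-up of the tissue. In the capsule and stroma list 17 of 18 genes were detected in both libraries, and the collagen genes led with Col3a1 at 3436 ± 670, Col1a1 at 1318 ± 257, Col6a1 at 526 ± 41.0 and Col1a2 at 286 ± 4.93 CPM (SD, n = 2). Col6a1 and Col1a2 had no reads on Known transcripts, and with Known, NIC and NNC transcripts Col1a2 stood at 28.8 CPM. Endothelial genes took 0.151% ± 0.00114 of reads, with 15 of 17 detected and Cldn5 at 321 ± 7.28, Plvap at 262 ± 1.54, Egfl7 at 187 ± 2.58 and Eng at 148 ± 17.8 CPM. Of 17 macrophage and immune genes 10 were detected in both, with Lyz2 at 101 ± 26.0, C1qa at 69.6 ± 17.2, C1qb at 63.65 ± 2.48 and C1qc at 56.0 ± 8.40 CPM. The haemoglobin genes Hba-a1 at 2095 ± 1044, Hbb-bs at 1132 ± 489, Hba-a2 at 496 ± 241 and Hbb-bt at 369 ± 200 CPM led the erythroid list, where 9 of 14 genes were detected in both libraries. These globin copies are near-identical pairs whose reads may be split either way.

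Growth-related groups were well represented. Of 32 cell cycle genes 30 had at least 10 reads in both libraries, led by H2afz at 515 ± 36.3, Mcm6 at 428 ± 79.5, Cdk4 at 407 ± 14.2 and Mcm2 at 320 ± 6.54 CPM (SD, n = 2). Of 30 imprinted genes 20 did, and Cdkn1c, a growth-restraining kinase inhibitor, stood at 4328 ± 866 CPM beside Gnas at 3609 ± 473, Meg3 at 696 ± 178 and Dlk1 at 657 ± 148 CPM. With Known transcripts alone, and scaled to Known reads, Cdkn1c stood at 1960 and Meg3 at 190 CPM, which are not parts of the levels above. Of 99 ribosomal protein genes 92 were detected in both, among them Rplp0 at 1321 ± 105, Rpl3 at 1312 ± 17.4 and Rpl4 at 1164 ± 111 CPM. Many processed pseudogenes resemble ribosomal protein genes, so their counts are uncertain. In the stress and immediate early list 17 of 23 genes were detected in both, with Jund at 930 ± 233, Junb at 184 ± 108, Nr4a1 at 130 ± 84.5 and Ier2 at 129 ± 33.9 CPM. Few reads fell on genes of the mitochondrial genome, 0.0328% of those on named genes in replicate 1 and 0.0214% in replicate 2. Of 15 such genes 6 were detected in both libraries, with mt-Co1 at 116 ± 11.4, mt-Cytb at 35.3 ± 18.6, mt-Rnr2 at 21.4 ± 1.05 and mt-Nd2 at 21.02 ± 13.4 CPM. Whether these low levels are those of the tissue was not tested.

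The 20 genes with the highest mean level took 7.32% of the reads on named genes in replicate 1 and 7.66% in replicate 2. Besides those named above they included Ubb at 4004 ± 199, the ATP synthase genes Atp5b at 3453 ± 275 and Atp5a1 at 2394 ± 388, Adh1 at 3190 ± 523, Hsp90ab1 at 2637 ± 346, Eef2 at 2289 ± 171, Actb at 1933 ± 135 and Hspa8 at 1899 ± 328 CPM (SD, n = 2). Xist, transcribed from the inactive X chromosome, had 64 and 41 reads, 0 of them on Known, NIC or NNC transcripts, and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 reads in both libraries, which allows up to 2.69 CPM in replicate 1 and 2.89 CPM in replicate 2.

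**Figure D1:**
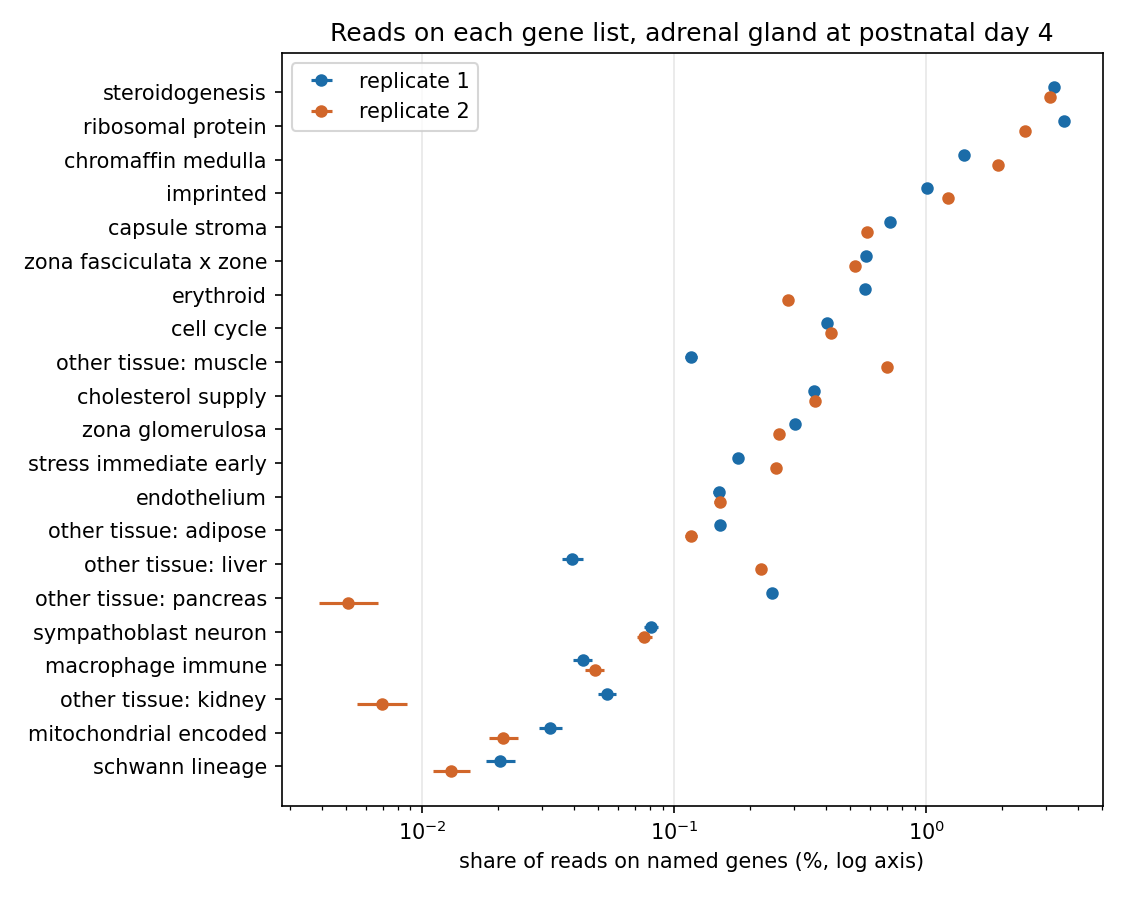
Share of the reads on named genes (percent, log axis) that fell on each gene list in replicate 1 and replicate 2, with Wilson 95% intervals. Steroidogenesis took 3.23% and 3.11% in the 2 libraries, while the pancreas list took 0.245% and 0.00510%.

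Detection and the spread between the 2 libraries were measured next. In all 19652 named genes had at least 1 read in either library, and 9630 had at least 10 reads in each, among them 19 of the 21 steroidogenesis genes. The biological coefficient of variation, the typical relative spread of a gene between the libraries beyond counting error, was 0.227 over 10467 genes with at least 20 summed reads (edgeR common dispersion). Across those genes the log2 CPM values of the libraries had a Pearson r of 0.884 and a Spearman rho of 0.918, a relation across genes, which are not independent replicates.

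The largest differences between the libraries were in genes of other organs. Transcripts of pancreatic digestive enzymes and hormones were present in replicate 1 and nearly absent from replicate 2. Insulin transcripts Ins2 and Ins1 had 667 and 265 reads against 0 and 0, at least 207-fold and at least 82.4-fold higher in replicate 1 (against the floor of 3 counts per library), though the 2 copies may share reads. Ctrb1, a chymotrypsinogen, was at least 185-fold higher, Pnliprp1 at least 163-fold, the elastases Cela2a and Cela3b at least 94.5-fold and at least 65.9-fold, Prss2 at least 64.7-fold, Cel at least 63.1-fold and Reg1 at least 54.4-fold. Clps, the colipase, had 741 reads against 1, a 691-fold ratio with a 95% counting interval of 124 to 27333. Ins2 (ENSMUSG00000000215.11) lies on chromosome 7 from 142678656 to 142743381 and Clps (ENSMUSG00000024225.5) on chromosome 17 from 28558149 to 28560766. Trypsin and elastase genes belong to multigene families, so the counts of single members are uncertain. All 10 tested genes of the pancreas list were higher in replicate 1, also when adjusted over the list alone, including Cela1, the only 1 of the 11 listed with at least 10 reads in both. Their median log2 ratio was 8.59, or 6.12 with the 8 genes at 0 reads set to their bound.

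Kidney genes went the same way. All 8 tested kidney genes were higher in replicate 1, and likewise when adjusted over the list alone, with a median log2 ratio of 3.42, or 3.06 with the 2 genes at 0 reads at their bound. The phosphate transporter Slc34a1 had 221 reads against 20, Miox 99 against 13, Pdzk1 74 against 17 and the water channel Aqp2 55 against 10, and 4 of the 15 listed genes had at least 10 reads in both libraries. Skeletal muscle genes went the other way, all 10 tested genes being higher in replicate 2 over all genes and adjusted over the list alone, with a median log2 ratio of -2.12. Acta1, skeletal actin, had 548 reads in replicate 1 and 3297 in replicate 2, Ckm, muscle creatine kinase, 260 and 1932, Tnnc2 145 and 748, and Mylpf 130 and 425, with 8 of 12 genes detected in both. Of the 12 liver genes, 8 of which were detected in both libraries, 10 were higher in replicate 2, 11 when adjusted over the list alone, with a median log2 ratio of -2.94. They were led by Trf, transferrin, with 246 and 1175 reads, Alb, albumin, with 36 and 339, Afp with 26 and 209, and Ahsg with 39 and 131. As shares of the reads on named genes, the muscle list held 0.117% in replicate 1 and 0.698% in replicate 2, and the liver list 0.0395% and 0.221%. The adipose list was present in both libraries, at 0.152% and 0.117%, with 9 of 14 genes detected in both and 3 of 10 tested genes higher in replicate 1, also 3 when adjusted over the list alone. Its leading members were Plin1 at 298 ± 15.3, the brown fat uncoupling gene Ucp1 at 273 ± 81.1, Fabp4 at 238 ± 130 and Cidea at 148 ± 13.7 CPM (SD, n = 2), and with Known, NIC and NNC transcripts Fabp4 stood at 157 CPM.

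The 10 genes with the largest ratios toward replicate 2 were a mixed set. The liver genes Fga, a fibrinogen chain, and Serpina1d were 60.0-fold (95% counting interval 10.3 to 2413) and 37.5-fold (6.31 to 1524) higher there, each on 1 read in replicate 1, and Serpina1d has close paralogs. The muscle genes Smtnl1 and Art1 were 33.2-fold (5.54 to 1355) and 19.3-fold (4.97 to 165) higher. Gm49450, a protein-coding gene on chromosome 15 from 98932137 to 98953551, had 6 reads against 136, a 24.3-fold ratio (10.9 to 67.4). The remaining 5 were the lincRNA AC154200.1, at least 28.2-fold higher, and the pseudogenes Gm49326, at least 10.4-fold, Gm6055, at least 9.65-fold, Gm11223, 26.8-fold (4.39 to 1101), and Gm6969, 18.2-fold (6.80 to 68.8). Reads of pseudogenes may belong to their parent genes.

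Over all genes, 1216 of 10467 differed between the libraries at an adjusted p under 0.05 (exact two-sided binomial test against the library totals, Benjamini-Hochberg), 689 higher in replicate 1 and 527 higher in replicate 2. Under edgeR's TMM scaling the split turned to 573 and 703, so the balance of directions rests on the scaling. Of these genes 461 differed at least 2-fold, 309 higher in replicate 1 and 152 in replicate 2, and 38 of the 461 belonged to the other-tissue lists. Those lists hold only part of the genes of these tissues, and Clps, Pnliprp1 and Reg1, for example, are outside them. The p-values compare these 2 libraries with counting noise, not conditions or populations.

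Genes of steroid synthesis and of chromaffin cells differed between the libraries in both directions. The steroidogenesis list had a median log2 ratio, replicate 1 over replicate 2, of 0.11 over 20 tested genes, inside the central 95% of 10000 random lists matched on expression (-0.22 to 0.16), with 5 genes higher in replicate 1 and 4 in replicate 2, counts that were equal when adjusted over the list alone. Fdx1, the ferredoxin that feeds electrons to the mitochondrial enzymes, was higher in replicate 1 (log2 ratio 0.37, counting SE 0.08), whereas Scarb1, which takes up lipoprotein cholesterol, and Fdxr were higher in replicate 2 (-0.46, SE 0.07, and -0.40, SE 0.07). Cyp11a1 had a log2 ratio of 0.17 that turned to -0.32 when only reads on annotated (Known) transcripts were counted, and the small ratios of Cyp21a1 (0.09) and Cyp11b1 (0.09) no longer passed the test under TMM scaling. With the trend of the ratios with transcript length removed, Fdx1 did not pass (0.15, SE 0.08, adjusted p = 0.284), and 4 genes of the list were higher in replicate 1 and 3 in replicate 2. The 4 were Cyp11a1 (0.24), Cyp21a1 (0.20), Cyp11b1 (0.13) and Cyp11b2 (0.37), and the 3 were Hsd3b1 (-0.09), Fdxr (-0.30) and Scarb1 (-0.39). The chromaffin list had a median of -0.19, at the 1.82 percentile of its random lists (-0.18 to 0.19), with 6 of 27 tested genes higher in replicate 2 and 2 higher in replicate 1, the same counts adjusted over the list alone. Chga (-0.51, SE 0.03), Chgb (-0.74, SE 0.03) and Th (-0.35, SE 0.04) were higher in replicate 2, Npy, a co-released peptide, was higher in replicate 1 (0.67, SE 0.10), and Pnmt did not pass the test (-0.11, SE 0.08). With the length trend removed, the ratio of Npy fell to 0.17 (SE 0.10, adjusted p = 0.361), none of the chromaffin genes was higher in replicate 1, and Pnmt was higher in replicate 2 (-0.24, SE 0.08, adjusted p = 0.0472). The muscle and liver lists were 5.99-fold and 5.59-fold higher in replicate 2, the library with the higher Chga and Chgb levels. Whether these differences are related was not tested.

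Immediate early genes were higher in replicate 2. The list had a median log2 ratio of -0.37, below its random lists (-0.21 to 0.27), and 5 of 19 tested genes were higher in replicate 2 with none in replicate 1, against 6 and 1 when adjusted over the list alone. The transcription factor genes Nr4a1 (-1.43, SE 0.19), Junb (-1.27, SE 0.16) and Jund (-0.52, SE 0.07) were among the 5, together with Ier2 (-0.54, SE 0.18), which did not pass with Known transcripts alone (-0.47), and Klf2 (-0.79, SE 0.25). Among imprinted genes 4 of 21 were higher in replicate 2 and 2 in replicate 1, with equal counts adjusted over the list alone, and the list median of -0.01 lay inside its random lists. H19 (-1.73, SE 0.13) had the largest ratio of that list toward replicate 2, with Cdkn1c (-0.41, SE 0.03), Dlk1 (-0.46, SE 0.08) and Gnas (-0.27, SE 0.03), while Mest (0.70, SE 0.13) and Meg3 (0.53, SE 0.08) were higher in replicate 1. The muscle list (5.99-fold) and the liver list (5.59-fold) were also higher in replicate 2, and a link to H19 or the immediate early genes was not tested.

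Red cell, ribosomal and mitochondrial transcripts were higher in replicate 1. The erythroid list had a median log2 ratio of 0.91 against random lists of -0.29 to 0.41, with 6 of 11 tested genes higher in replicate 1, 7 adjusted over the list alone, among them Hba-a1 (1.06, SE 0.05), Hbb-bs (0.91, SE 0.06) and the anion exchanger Slc4a1 (2.96, SE 0.72). With the length trend removed Hba-a1 stood at 0.70 (SE 0.05) and Hbb-bs at 0.47 (SE 0.06), both still past the threshold, and the list median at 0.61. The ribosomal protein list had a median of 0.51 against -0.13 to 0.03, with 61 of 93 genes higher in replicate 1 and 3 in replicate 2, or 66 and 3 adjusted over the list alone, and 27 and 4 with the length trend removed. The mitochondrial list had a median of 0.91 against -0.37 to 0.56, with 3 of 6 genes higher in replicate 1 by both counts, on 360 and 218 reads. With the length trend removed its median was 0.88, still above its random lists (upper limit 0.50), while none of its genes passed, as mt-Cytb went from 1.11 to 0.98 (SE 0.36, adjusted p = 0.0590) and mt-Nd2 from 1.36 to 1.22 (SE 0.48, adjusted p = 0.0704) on few reads. The pancreas and kidney lists were 48.0-fold and 7.81-fold higher in the same library, and a link to the erythroid, ribosomal and mitochondrial lists was not tested. Short transcripts as a whole moved with these lists: 489 genes with transcripts of up to 750 bases had a median log2 ratio of 0.49. The 4855 genes of 2000 to 4000 bases had a median of -0.03, and the 2037 genes over 4000 bases one of 0.09. The ERCC spike-ins, synthetic RNAs added to each sample, did so too. The 8 of up to 750 bases had a median of 0.64 and the 14 of 1000 bases or more a median of 0.14 (exact permutation test of the difference of medians, two-sided p = 0.00198). The 5 spike-ins of 750 to 1000 bases, which that test left out, had a median of 0.47.

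The medians of the other lists lay inside their random lists. They were 0.31 for the zona glomerulosa (5 of 13 genes higher in replicate 1 and 1 in replicate 2), 0.28 for the zona fasciculata and X zone (3 of 6 and 0), 0.09 for cholesterol supply (3 of 27 and 0), 0.03 for capsule and stroma (3 of 17 and 0), 0.25 for adipose tissue (-0.01 with the length trend removed) and 0.53 for the Schwann lineage (1 of 7 and 0). Adjusted over the list alone, the counts differed for cholesterol supply with 4 higher in replicate 1, and for capsule and stroma with 1 higher in replicate 2. In the adipose list 3 genes were higher in replicate 1 and 0 in replicate 2, or 3 and 1 with the length trend removed. The cell cycle list had a median of -0.04, with 2 of 31 genes higher in replicate 1 and 1 in replicate 2, or 2 and 3 adjusted over the list alone. None of the 16 endothelial, 11 macrophage and immune or 12 neuronal genes tested passed, also when adjusted over the list alone, with medians of -0.04, -0.08 and 0.07, although Lyz2 was higher in replicate 2 under TMM scaling (-0.59). The isoform panel had a median of -0.07, with 7 of 42 genes higher in replicate 1 and 13 in replicate 2, or 7 and 14 adjusted over the list alone, and 4 and 12 with the length trend removed. Of 22 lists with at least 5 tested genes 9 lay outside the central 95% of their random lists. With Known transcripts alone the medians of the zona glomerulosa (0.59) and of the zona fasciculata and X zone (0.40) lay outside as well, and with Known, NIC and NNC transcripts so did those of the zona glomerulosa (0.49), of the zona fasciculata and X zone (0.40) and of steroidogenesis (0.19). With the length trend removed the median of the zona glomerulosa was 0.37, also outside (upper limit 0.32).

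**Figure D2:**
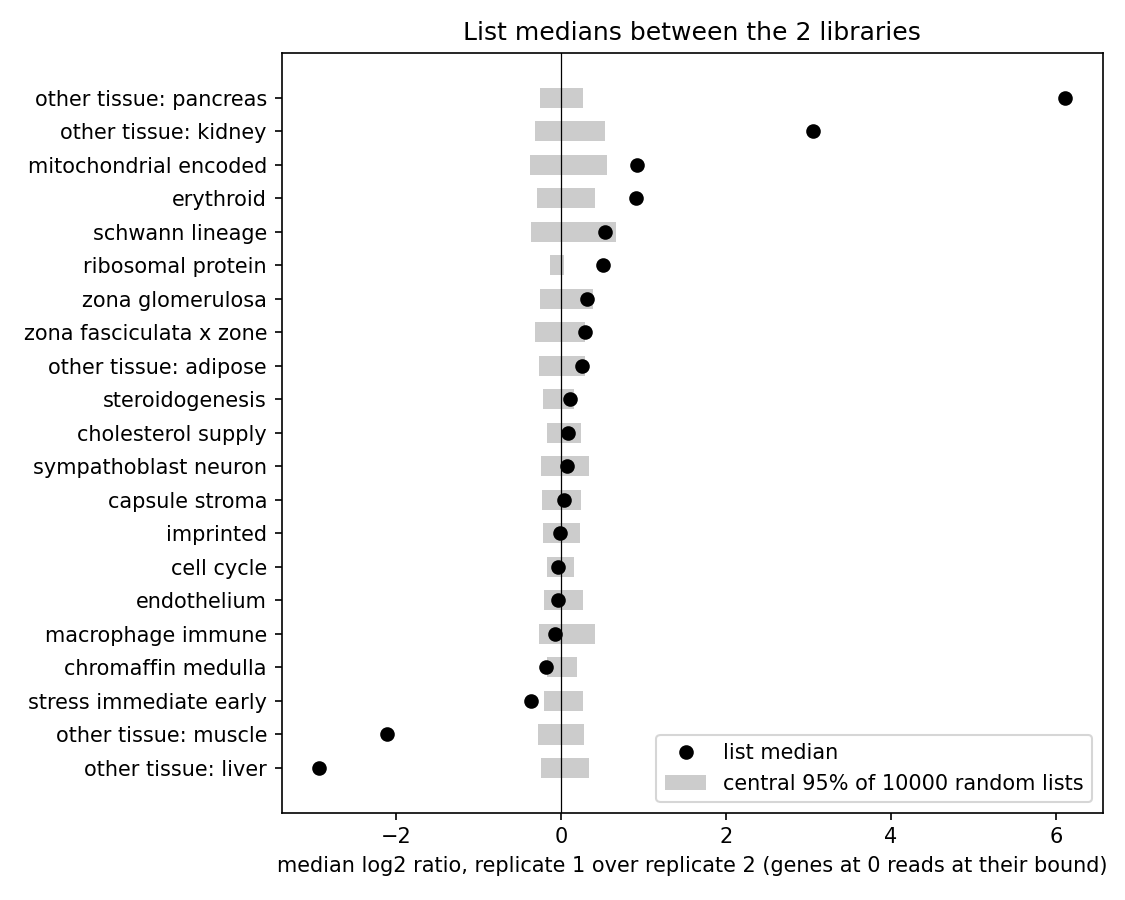
Median log2 ratio, replicate 1 over replicate 2, of the tested genes of each list (points, with genes at 0 reads in a library at their bound) and the central 95% of 10000 random lists matched on expression (grey bars). The pancreas median is 6.12 and the liver median -2.94, while steroidogenesis at 0.11 lies inside its bar.

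**Figure D3:**
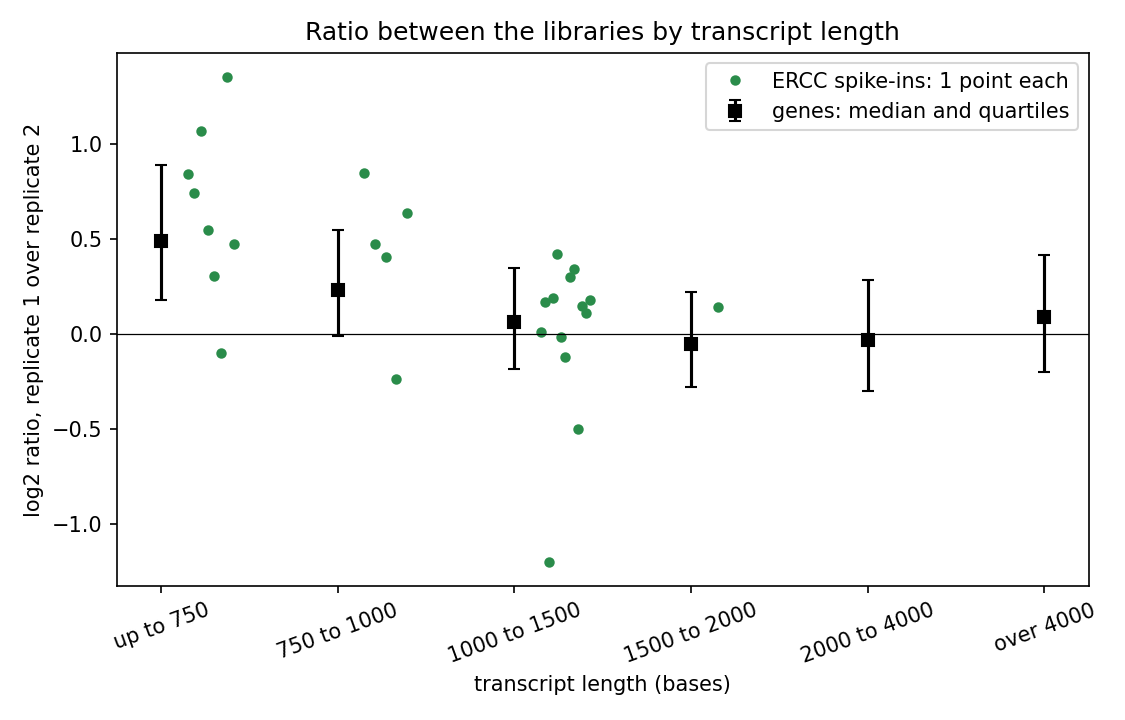
Log2 ratio, replicate 1 over replicate 2, by transcript length in bases, as the median and quartiles of the genes in each length class (squares and bars) and as 1 point for each ERCC spike-in with at least 20 summed reads. Genes of up to 750 bases have a median of 0.49 and those of 2000 to 4000 bases a median of -0.03.

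Long reads also placed each read in a transcript class. Known transcripts, which match every annotated splice junction, took 66.3% of reads in replicate 1 (Wilson 95% interval 66.2 to 66.4) and 70.8% in replicate 2 (70.7 to 70.9). Incomplete splice matches (ISM), which hold part of an annotated transcript, took 11.97% and 11.3%, new combinations of annotated splice sites (NIC) 5.47% and 5.59%, and models with at least 1 unannotated splice site (NNC) 3.58% and 3.57%. Reads over unspliced or intronic sequence (Genomic) took 6.33% (6.29 to 6.37) in replicate 1 and 4.07% (4.03 to 4.11) in replicate 2, Antisense models 5.60% and 4.17%, and Intergenic models 0.743% and 0.438%. Each class but NNC differed between the libraries beyond counting noise (Fisher's exact test, Benjamini-Hochberg over 7 classes), and for NNC the adjusted p was 0.565. Among ISM reads, 64.2% in replicate 1 and 68.6% in replicate 2 lacked the 5' part of their transcript (Suffix), while 12.7% and 14.0% lacked the 3' part (Prefix).

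The class of the reads differed strongly from gene to gene among the most abundant ones. The chromogranin gene Chgb had 90.6% Known reads in replicate 1 and 94.1% in replicate 2, Th 89.0% and 89.7%, and Cyp21a1 75.5% and 75.1%. Hsd3b1 had only 0.251% and 0.456%, and 77.1% (75.9 to 78.3) and 80.1% (79.0 to 81.2) of its reads fell on 1 ISM model with 4 exons, so that its level was 21.9 CPM with Known transcripts alone. That model began in the exon at 98858152 to 98858341 on chromosome 3 (minus strand) and lacked the annotated exon at 98859672 to 98859794. Cyp11a1 had 39.0% (38.04 to 40.002) of its reads on an unspliced model with 1 exon in replicate 1 and 18.1% (17.3 to 18.98) in replicate 2. Cdkn1c had more NIC than Known reads, 51.9% against 32.4% in replicate 1 and 50.1% against 33.1% in replicate 2. Hsd3b1, Cyp11a1 and Cdkn1c were singled out after their values were seen.

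**Figure D4:**
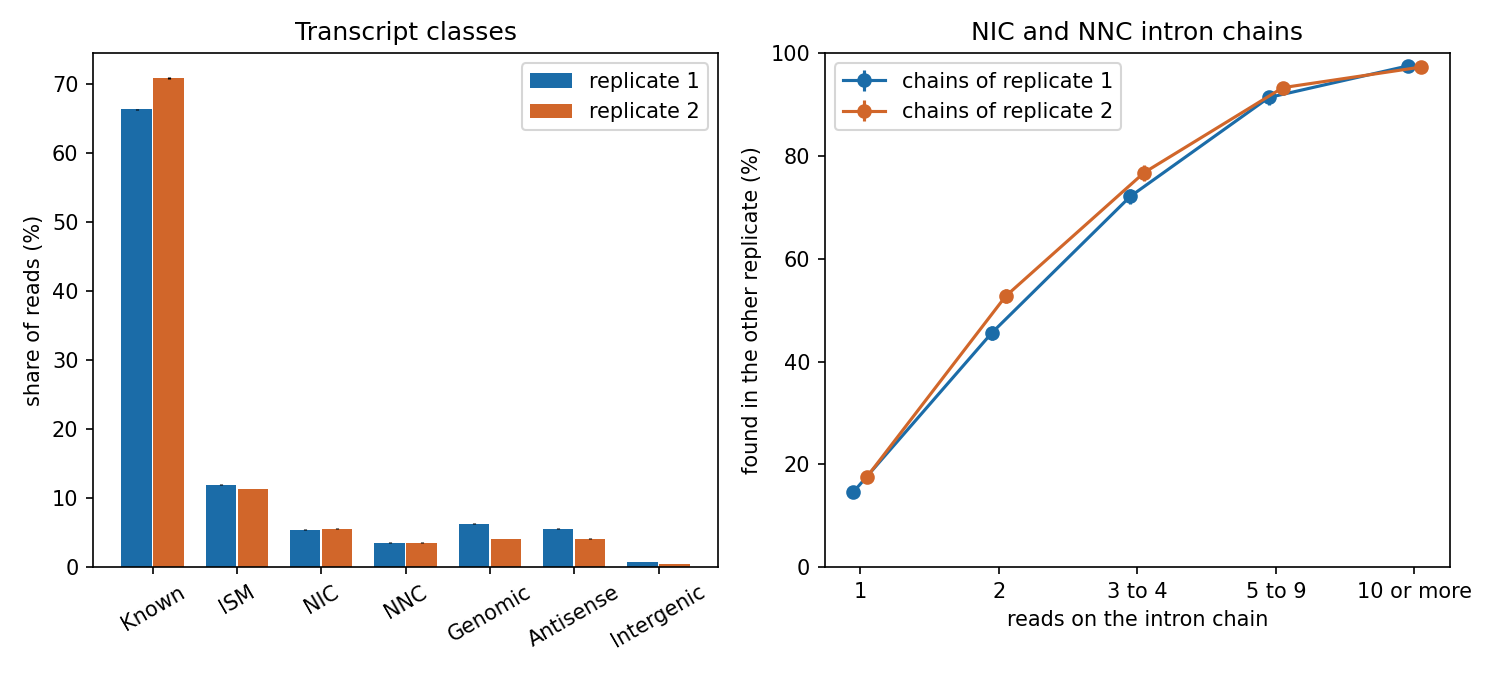
Left, share of all reads (percent) in each transcript class for replicate 1 and replicate 2, with Wilson 95% intervals; right, share of NIC and NNC intron chains found in the other replicate (percent), by the number of reads on the chain. Known transcripts took 66.3% and 70.8% of reads, and chains with 10 or more reads were shared in 97.47% and 97.3% of cases.

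In most genes 1 transcript held most of the Known reads. Among 5524 genes with at least 20 Known reads in each library, the dominant Known transcript held a median of 98.1% of the Known reads, and in 3983 genes it held 90% or more. Of these 5524 genes 1876 had reads on 1 Known transcript only, which holds 100% by definition, and among the other 3648 the median was 93.1%, with 2107 genes at 90% or more. In 175 genes it held at most 50%. The most abundant transcript was the same in both libraries for 5398 genes. In the isoform panel 35 of 42 genes had enough reads, and 21 had a dominant share above 90%, including 100% in both libraries for Star, Cyp21a1, Cyp11b1, Chgb, Th, Dbh and Nr0b1, each with reads on 1 Known transcript only. Nr5a1, the master regulator of steroidogenic cells, used Nr5a1-201 for 96.3% ± 0.0543 of its Known reads (SD, n = 2). Most reads of Nr5a1 and Dbh were of other classes, so that Nr5a1-201 held 23.9% ± 3.09 and Dbh-201 28.8% ± 1.51 of all reads of their genes.

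The other 14 panel genes divided their Known reads. Gnas, encoding the stimulatory G protein alpha subunit, used Gnas-208 for 76.2% ± 1.06 (SD, n = 2), with Gnas-207 at 9.46% ± 0.497. Cdkn1c used Cdkn1c-201 for 79.6% ± 0.0455 of its Known reads, but for 27.2% once its NIC and NNC reads were counted, Scarb1 Scarb1-201 for 88.0% ± 1.39 and Dlk1 Dlk1-205 for 76.1% ± 1.59. Hmgcs1 was split between Hmgcs1-201 at 59.4% ± 1.24 and Hmgcs1-202 at 40.5% ± 1.08. Vegfa used Vegfa-202 for 53.0% ± 1.94 (32.1% ± 3.27 of all its reads) and Vegfa-201 for 37.7% ± 2.04, and Aplp2 used Aplp2-201, with 17 exons, for 61.8% ± 2.00 and Aplp2-209, with 16 exons, for 36.3% ± 1.68. App was spread over App-206 at 37.6% ± 0.560, App-202 at 24.1% ± 0.821 and App-203 at 15.3% ± 0.483. Meg3 used Meg3-205 for 77.8% ± 4.37 of its Known reads, but for 31.2% once NIC and NNC reads were counted and for 15.1% ± 0.0996 of all its reads, Clta Clta-206 for 85.1% ± 5.42 and Rtn4 Rtn4-202 for 80.3% ± 0.956. Myl6 had equal summed reads on Myl6-201, at 42.7% ± 4.40, and Myl6-206, at 43.9% ± 8.39. The other two, Pkm and Tpm1, differed between the libraries.

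Isoform usage differed between the libraries for 18 of 3648 genes (Fisher's exact test of the dominant against the other Known transcripts, Benjamini-Hochberg at 0.05). Tpm1-205 held 55.6% of Tpm1 Known reads in replicate 1 and 88.1% in replicate 2 (adjusted p = 2.17e-15, exact), and Tpm2-202 held 54.8% and 86.1% of those of Tpm2. The muscle list was 5.99-fold higher in replicate 2, and a link to Tpm1 and Tpm2 was not tested. Pkm-201 of the pyruvate kinase gene held 77.4% and 67.8%. In Rpl5 and Atf4 the retained-intron transcripts Rpl5-204 and Atf4-203 were favoured in replicate 1, with 75.6% against 46.9% and 66.0% against 29.1%. The largest difference was in Slc37a4, where Slc37a4-201 held 67.7% of 31 Known reads in replicate 1 and 9.09% of 33 in replicate 2. In the isoform panel 3 of 25 tested genes, Tpm1, Tpm3 and Pkm, passed, and 4 did when adjusted over the list alone.

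Many unannotated splice combinations occurred in both libraries. Replicate 1 held 57574 NIC and NNC intron chains and replicate 2 held 49743, and 14207 chains were identical at every splice site in both. They made up 24.7% (24.3 to 25.03) of the chains in replicate 1 and 28.6% (28.2 to 29.0) in replicate 2, but carried 55.0% and 60.2% of the NIC and NNC reads. Of the chains with 1 read, 14.6% in replicate 1 and 17.6% in replicate 2 were found in the other library. At 1 read per chain NIC chains were shared more often than NNC chains, in 19.1% (18.6 to 19.7) against 10.6% (10.2 to 11.01) of cases in replicate 1 and 23.3% (22.7 to 23.95) against 12.8% (12.4 to 13.3) in replicate 2 (Fisher's exact p = 1.91e-146 and 5.73e-162), whereas at 10 reads or more the shares were 97.4% (96.0 to 98.3) and 97.6% (94.9 to 98.9) in replicate 1 (p = 1.00) and 97.4% (96.0 to 98.4) and 96.7% (93.3 to 98.4) in replicate 2 (p = 0.631).

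For several genes such a chain held most of the reads. Whether these chains are separate splice forms of the tissue was not tested. Oaz1 and Oaz2, which encode the antizymes that limit polyamine synthesis, had 91.9% ± 0.934 and 86.4% ± 1.64 (SD, n = 2) of their reads on 1 NIC chain of 5 exons each. The chaperonin gene Cct6a had 84.4% ± 0.332 of its reads on an NNC chain of 13 exons, and the collagen gene Col6a1 66.2% ± 1.93 on an NNC chain of 32 exons. Atp2a1, the calcium pump of fast muscle, had 69.1% ± 1.29 on a chain of 22 exons that was classed as NIC in both libraries but had 1 splice site outside the gene's annotation, with 339 reads in replicate 1 and 1379 in replicate 2, where the muscle list was 5.99-fold higher. Ctbp1 had 59.2% ± 3.36 on a NIC chain of 10 exons, and the chromaffin granule gene Cyb561 48.4% ± 2.13 on a NIC chain of 6 exons. The 10 most abundant shared chains included 3 of Cdkn1c, at 30.3% ± 1.32, 10.4% ± 0.439 and 9.25% ± 0.655 of its reads, all with 4 exons between 143458339 and 143460996 on chromosome 7. The most abundant of these had no splice site outside the gene's annotation, and the other two had 1 such site each and were classed as NIC in one library and NNC in the other. The Oaz1 chain spanned 80826656 to 80829284 on chromosome 10.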

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

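Among the tests in this part, those on strand, on the spike-ins by length and on the length trend in the other-tissue lists were chosen only after the result was seen, as was that on reads of another library, and the removal of the length trend from gene ratios was also chosen after seeing the data.

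Antisense models, which the gene counts do not use, held signal in both libraries, with no control sample to compare. The most abundant one of each library, without introns, lay on chromosome 17 (minus strand) opposite the lincRNA gene Gm26917 and beside an annotated rRNA gene, from 39843013 to 39846245 with 5820 reads in replicate 1 and from 39843013 to 39845444 with 7491 reads in replicate 2. Antisense models on ERCC spike-ins had 212 reads in replicate 1 and 213 in replicate 2, on 4 spike-ins that had no sense reads, and whether the reference sequences of these 4 are in the other orientation was not tested, so these reads need not be antisense.

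Antisense models took 68157 reads in replicate 1 and 46168 in replicate 2 outside the spike-ins, with 97.1% and 96.8% of them on models of 1 exon. Sense reads that lost their strand are argued against by the spike-ins with sense reads. These had 0 antisense reads in either library, an upper limit of 0.0157% in replicate 2. The 4 spike-ins with antisense reads alone were outside this comparison, so it does not speak for them. Fragments of the host gene's exons remain open, because 37.5% of antisense reads (mean of both libraries) lay inside 1 exon of the opposite-strand gene, or 28.7% in replicate 1 and 28.6% in replicate 2 without the locus opposite Gm26917, all between the values set for and against it (50% and 10%). No biological explanation was tested.

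The pancreas and kidney lists were higher in replicate 1 and the muscle and liver lists higher in replicate 2. The transcript length trend is argued against, since the smallest of the 4 absolute list medians was 2.27 (log2) after the trend was removed. Pieces of neighbouring tissue in the dissected gland are a candidate explanation: in second lists of the same tissues 27 of 31 tested genes, 87.1%, lay at least 2-fold in the same direction, and the exceptions included the liver gene Apoc4, which was higher in replicate 1 (log2 ratio 0.99), and the kidney genes Podxl and Slc27a2, which stayed under 2-fold. The most abundant listed genes were Ins2 with 667 and Slc34a1 with 221 reads in replicate 1 and Acta1 with 3297 and Trf with 1175 in replicate 2, none of the listed genes was in another list, and 4 kidney, 8 liver, 8 muscle and 1 pancreas genes had at least 10 reads in both libraries. Reads of another library sequenced beside these cannot be told apart from this for any of the 4 lists, since both would bring the same transcripts. The second lists do not separate them either. The pancreas list held 0.245% of the reads on named genes in replicate 1. A difference between animals was not tested.

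Short transcripts were higher in replicate 1. Base composition is argued against as the main cause: across 3417 genes under 2000 bases the partial rank correlation of the log2 ratio was -0.14 with GC content at equal length and -0.36 with length at equal GC content. A difference in size selection or read length may account for it, since spike-ins of up to 750 bases exceeded those of 1000 bases or more by 0.50 (log2). With the trend removed the erythroid list kept a median of 0.61 and the ribosomal protein list one of 0.19, both above their random lists (upper limits 0.33 and 0.02), so length alone did not account for the erythroid list, and for ribosomal genes the median fell from 0.51. What remains of both is open, a difference between the animals included, which was not tested.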

How the results depend on the processing

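The removal of the length trend and of the listed other-tissue genes was chosen after seeing the data. Of the values for single genes, lists and isoforms in settings that could change them, 937 kept their direction and call or moved by less than the spread, 107 moved by more, 30 lost a call, 14 gained a call and 2 reversed. Leaving out a replicate or the mitochondrial genes, and another scaling for lists, are not counted, as their 532 values were all but fixed beforehand. Genes differing between the libraries numbered 933 to 1276 in the other settings and 773 at a threshold of 0.01, which is stricter by construction. Genes differing 2-fold numbered 291 with a minimum of 50 summed reads, which tests fewer genes, and 369 to 472 otherwise. With the genes of the first and second other-tissue lists left out the counts were 1143 and 392, and 1127 of the 1143 genes also differed with them. Genes of those tissues outside the lists, such as Clps, Pnliprp1 and Smtnl1, stayed in. This setting therefore cannot show whether the remaining differences come from other tissues. Higher genes in replicate 1 made up 56.7% of calls, 44.9% under TMM and 52.1% under DESeq2 scaling. The number of lists outside their random lists ranged from 7 to 12 against 9, and no list changed sign among those outside. The biological coefficient of variation was 0.239 with Known transcripts alone. Genes detected in both libraries numbered 15674 at 1 read, a lower bar. Steroidogenesis took 2.68% of the reads on Known transcripts and 2.60% of those on Known, NIC and NNC transcripts, as Hsd3b1 and Cyp11a1 lost ISM and Genomic reads. The log2 ratio of Cyp11a1 reversed to -0.32 and -0.31 in these 2 settings, which leave out Genomic reads, 39.1% of its reads in replicate 1 and 18.3% in replicate 2. With models of at least 2 exons, Known took 76.6%, NIC 6.73%, NNC 4.35%, Genomic 0.143%, Antisense 0.180% and Intergenic 0.0477%, since models of 1 exon leave the total. Without spike-ins and mitochondrial genes NIC took 5.64% and NNC 3.65%. The median dominant isoform share fell to 87.8% with NIC and NNC reads in the total and was 98.0% to 98.5% without either replicate. Shared chains numbered 5229 at 2 reads and 1618 at 5 reads in each library, and 17739 with splice sites within 5 bases. With 2 replicates, leaving either out gives the other's value, which says nothing on stability: steroidogenesis 3.11% to 3.23%, Known 66.3% to 70.8%, ISM 11.3% to 11.97%, NIC 5.47% to 5.59%, NNC 3.57% to 3.58%, Genomic 4.07% to 6.33%, Antisense 4.17% to 5.60% and Intergenic 0.438% to 0.743%. Genes with differing isoform usage numbered 16 to 25 against 18. Where no reason is given above, the cause was not tested. Depth limits the isoform test, where 20 Known reads in a library show only large shifts.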

Other observations

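The test of the Genomic share per gene was chosen only after the class shares were seen. Unspliced reads were more frequent in replicate 1 across many genes. Among 2289 genes with at least 100 reads in each library, the Genomic share was higher in replicate 1 for 1314 genes and in replicate 2 for 591, past an adjusted p of 0.05 for 346 and 79 (Fisher's exact test, Benjamini-Hochberg). Star, which delivers cholesterol to the mitochondrion, had 20.2% of its reads in that class in replicate 1 and 0.434% in replicate 2, Apoe 27.8% and 14.8%, and Slc25a3 31.4% and 11.5%. The direction was opposite for Tuba1b, with 0% and 14.5%, and for Sdc3, with 0.433% and 90.4%. Each library's models were built separately, so the class of a gene's reads can change with the model they were given to. These genes were chosen after their values were seen.

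Antisense reads also lay at the 3' end of Actb, where a model without introns on chromosome 5 from 142901399 to 142903654 had 784 reads in replicate 1 and a different one from 142901122 to 142903501 had 589 reads in replicate 2. A model with the same ends in both libraries lay inside an exon of Gnb1, with 289 and 252 reads.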
